A study of Rattus norvegicus with 16 samples.

How the data were processed

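Liver mRNA of male Lewis rats aged 3, 9, 12, 18 and 24 months was measured on 16 one-colour whole-genome rat arrays, 1 per sample. The rats were kept on a 12-h light and dark cycle with free food and water, and the livers were frozen in liquid nitrogen. Whether each sample is a separate animal is not stated, nor is the hour of tissue collection. Groups followed the stated age. The labelling kit named by the authors is one for microRNA although the array measures mRNA, and this was not resolved.

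Per the file headers, the signal, mean signal and local background columns were made with Agilent Feature Extraction 10.7.3.1 and hold intensity values with no normalization between arrays. The well-above-background, saturation and outlier flags are columns of another kind (other), per the file headers. The series table deposited by the authors holds log2 values normalized between arrays in a way that is not stated, and it served as an alternative alone. Gene names came from a table of a later genome build than the one the headers name, so no positions are given. Of the probes, 18028 were named through their accession, and 19416 kept the name given with the array.

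The processed signal was taken to log2, and the 75th percentile of each array was subtracted. Spots with an outlier flag were set to missing, spots of a probe were averaged, and 37 values stayed missing. A probe was kept if it lay well above background on all arrays of at least 1 age, which left 25682 of 41012 probes, 19885 of them above background on all 16 arrays. A gene was represented by its probe with the highest mean, which gave 21447 genes, 11557 with a symbol. Of 3380 genes with over 1 kept probe, 4 had called probes in both directions. Values are log2 signal relative to the 75th percentile, as mean ± SD between arrays, with n = 4 at 24 months and n = 3 at the other ages. Where a group did not lie above background, a change is given as at least the fold against the background limit. That limit is the lowest value among the well-above-background probes of an array. The bound holds for the main processing alone, and alternatives gave smaller changes. Signal over background is the depth of these data: 52.5% to 65.2% of probes per array lay well above it, and the coefficient of variation of replicate spots was 4.67% to 5.92%.

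A model with a mean per age was fitted across all genes with limma 3.58.1 in R 4.3.3 and data.table version 1.17.8, and contrasts were tested with its moderated statistics, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Contrasts were 24 against 3 months, each step between neighbouring ages, any age difference (F test) and a linear trend. Brackets after a gene give the adjusted p over all genes. The 33 gene lists, written from general knowledge before the data were examined and with at least 5 measured members each, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other genes. Fry tests whether the genes of a list move, on balance, in 1 direction, and compares them with no other genes. Adjustment was over the 33 lists. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

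The genes to name were set by a rule before the data were examined: among called genes with a symbol and above background on every array of both groups, the 10 with the largest rise and the 10 with the largest fall for 24 against 3 months and the trend, and 5 of each for the steps, then up to 4 members per list with the smallest adjusted p for 24 against 3 months, and up to 3 genes each way measured at 1 age alone. List members named for the steps, and names that complete a count of few genes, were chosen after their values were seen. Some genes that the rule picks are not reported here, and none was put in their place.

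Alternatives set before the data were examined were quantile normalization, normexp background correction with an offset of 50, the series table, no filter, a filter on all arrays, the mean of a gene's probes, slide or replicate number as a block, fits on the compared ages alone, log2 age, a fold of at least 2, and leaving out each array. Scan session as a block, fits within a slide, scan day or session, and leaving out 24-month arrays 3 and 4 together were added after seeing the data. Tested on simulated changes for 24 against 3 months, the procedure called 70 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, with 11 false calls among 174. For the steps, it called from 48 of 100 (12 against 9 months) to 58 of 100 (24 against 18 months) at 2-fold. Both of 2 changed lists were called, and 0 others. This simulated result does not show how often lists pass falsely in the measured data. There 19 of 35 splits of the 3-month and 24-month arrays, the real split included, gave at least 12 lists. With an estimated correlation 0 lists passed for 24 against 3 months.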

Results

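Messenger RNA was measured in liver of male Lewis rats of 5 ages on 16 one-colour arrays, 1 array per sample. There were 3 samples at 3 months, 3 at 9 months, 3 at 12 months, 3 at 18 months and 4 at 24 months. Between 52.5% and 65.2% of the probes of an array lay well above background, lowest on 24-month array 4 and highest on 3-month array 3. The 75th percentile of the signal was between 171 and 412 intensity units. No spot was saturated, and the number of arrays limits the precision of each value. The median SD of a gene between arrays was taken over the 16545 genes well above background on all 16 arrays. On the log2 scale it was 0.084 at 3 months, 0.151 at 9 months, 0.289 at 12 months, 0.131 at 18 months and 0.258 at 24 months. Slide and age cannot be told apart in this spread. All arrays of 3 months lay on slide 1 and all of 18 months on slide 4. Those of 9 months lay on slides 1 and 2, of 12 months on 2 and 3, and of 24 months on 5, 6 and 7. The median SD of replicate spots within a 3-month array was 0.106. Whether the 3-month arrays come from separate animals cannot be told from these values. The first 2 principal components held 29.0% and 20.2% of the variance. The arrays of 12 months replicate 2, 24 months replicate 3 and 24 months replicate 4 stood apart from their groups, with mean correlations across genes of 0.962, 0.970 and 0.969 to the other arrays of their age. Each of them lay on a slide that held no other array of its age. For 12 months replicate 2 the scan day and session differed too. Whether the sample or the batch set them apart cannot be told. Ages were spread unevenly over 7 slides, 3 scan days and 2 scan sessions. The 3-month and 24-month arrays shared a scan session but no slide or day. The 18-month and 24-month arrays shared no slide, day or session.

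The comparison of 24 with 3 months asked which liver transcripts differed over the widest span of ages. At 24 months the liver held more mRNA of 11 of 18 clock genes and of 5 of 9 MHC class II genes, which present antigen. It held less mRNA of 15 of 34 interferon-induced genes and of 14 of 31 genes of cell division. As lists, these did not pass with an estimated correlation (adjusted p = 0.517 for clock genes, 0.590 for the others). For clock genes the hour of tissue collection, which is not stated, cannot be told apart from age. Its part in changes of other genes was not tested. The clock output factor Dbp (NCBI gene 24309) had a log2 signal of -0.59 ± 0.40 (SD, n = 3) at 3 months and 4.11 ± 1.02 (SD, n = 4) at 24 months, 25.9-fold higher (adjusted p = 2.12e-05). Fbp2, the muscle form of fructose bisphosphatase, was 17.8-fold higher, from -2.78 ± 0.23 to 1.38 ± 0.33 (adjusted p = 1.78e-06).

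By limma, 2858 of 21447 genes differed between 24 and 3 months, 907 higher and 1951 lower at 24 months. Of the called genes, 1557 changed at least 2-fold. Other large rises were those of the imprinted long non-coding RNA H19 (18.2-fold, adjusted p = 0.00272), the clock-linked repressor Bhlhe41 (12.1-fold, 8.88e-05), the ubiquitin-like modifier Ubd (11.7-fold, 0.000227) and the membrane protease Adam8 (9.33-fold, 0.00316). The clock gene Per2 was 9.25-fold higher (0.000384), the clock-controlled protease Usp2 8.09-fold (0.00275), the class II invariant chain Cd74 7.64-fold (0.000901) and Cml3 8.2-fold (0.0333). Of the falls, the urinary carrier protein Obp3 was 11.9-fold lower (0.0358), the clock activator Bmal1 10.3-fold (0.00801), the ribosomal protein gene Rps26 9.57-fold (0.000249) and the stress-induced Gadd45g 8.77-fold (0.00029). Bmal1 fell from 2.23 ± 0.11 to -1.13 ± 1.18, and Gadd45g from 6.51 ± 0.15 to 3.38 ± 0.36. The receptor Notch1 was 6.36-fold lower (0.0101), the interferon regulator Irf7 5.69-fold (0.000274), the repressor Etv3 5.64-fold (0.000411), Ly6c 5.2-fold (0.00292), Ly6i 5.18-fold (0.000755) and Mx2 5.15-fold (0.0019). Whether the probes of Obp3, Rps26 and the Ly6 genes also read related genes or pseudogenes was not tested. The call of Cml3 was lost without any of 3-month arrays 1, 2 and 3 or 24-month arrays 1 and 2 (adjusted p up to 0.104). That of Obp3 was lost without any of 3-month arrays 1, 2 and 3 or 24-month array 2 (up to 0.105).

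Some genes lay above background at 1 of these ages alone. The pancreatic protease gene Cpb1 was at least 30.4-fold higher at 24 months, the transcription factor Pou3f3 at least 7.91-fold and the eosinophil ribonuclease Rnase3 at least 7.26-fold. Above background at 3 months alone were the RNA-binding protein Igf2bp2 (at least 5.09-fold lower at 24 months), the vomeronasal receptor Vom2r79 (at least 4.79-fold) and Vwa5b2 (at least 4.61-fold). Over the alternatives run, the smallest log2 changes were 2.26 for Cpb1, 1.36 for Pou3f3 and 1.44 for Rnase3. They were -0.56 for Igf2bp2, -0.58 for Vom2r79 and -0.41 for Vwa5b2, so these bounds hold for the main processing alone. Among genes with a symbol past the threshold, those measured on every array of 24 months and on none of 3 months numbered 12, against 210 with the opposite pattern. Fewer probes lay well above background on the 24-month arrays (52.5% to 60.5%) than on the 3-month arrays (61.7% to 65.2%).

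Of the 33 gene lists, 12 passed the set test, 6 higher and 6 lower at 24 months. Counts in brackets were adjusted over the list alone. None of the 12 passed with an estimated correlation, and 19 of 35 splits of these arrays gave as many lists. With normexp 17 passed, 3 higher and 14 lower, 9 of them among the 12. Cholesterol synthesis, T and NK cell and acute phase genes did not pass without 24-month array 2, the former 2 also not without array 3, and the latter also not without array 1. Neutrophil and matrix genes did not pass without array 4. Of 34 interferon-induced genes 15 fell (16 in the list alone), with a median log2 change of -0.75 (adjusted p = 1.67e-06, adjusted p = 0.590 with an estimated correlation). Ifi44 fell from 3.07 ± 0.02 to 2.09 ± 0.17 (0.000469) and Ifi27 from 7.58 ± 0.02 to 6.59 ± 0.26 (0.000837). Of 31 cell cycle genes 14 fell (18 in the list alone), median -0.89 (adjusted p = 1.23e-05, 0.590 with an estimated correlation), among them Cdc20 (from 0.28 ± 0.05 to -1.21 ± 0.43) and Plk1 (from 0.74 ± 0.11 to -0.88 ± 0.73). The cell cycle score of 24-month array 2 (0.85) lay within the range of the 3-month arrays (0.82 to 0.96), and those of the other 24-month arrays were -0.52, -0.19 and -0.44. Of 28 genes of stellate cells, fibroblasts and matrix, 5 fell (7 in the list alone), median -0.34 (adjusted p = 0.0102, 0.616 with an estimated correlation): Col1a2, Col3a1, Fn1, Pdgfrb and Timp1. Col3a1 fell from 4.36 ± 0.06 to 3.25 ± 0.12 (0.000163). Of 10 neutrophil genes 3 fell (4 in the list alone), median -1.30 (adjusted p = 0.0119, 0.694 with an estimated correlation). These were Camp, Mpo and Fcnb, and Fcnb fell from 0.73 ± 0.07 to -0.72 ± 0.66. The neutrophil score of 24-month array 3 (2.43) went the other way, above the 3-month arrays (1.53 to 2.12), while the others were at -0.14, -0.44 and -1.23. Of 25 acute phase genes, Hpx and C3 fell (0 in the list alone), median -0.33 (adjusted p = 0.0168, 0.590 with an estimated correlation). The acute phase score of 24-month array 3 (0.68) lay above the 3-month arrays (0.32 to 0.47), while the others were at -0.10, -0.11 and -0.03. Of 17 male-biased genes, Cyp2c13, Obp3 and Rup2 fell and Spink3 rose (6 and 1 in the list alone), median -0.84 (adjusted p = 0.0067, 0.694 with an estimated correlation). Their scores were -0.95 and -1.60 on 24-month arrays 2 and 3 but 0.02 and -0.13 on arrays 1 and 4, against 0.18 to 0.30 at 3 months.

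Of 18 clock genes 11 rose and 2 fell (11 and 3 in the list alone), with a median log2 change of 0.85 (adjusted p = 5.45e-05, 0.517 with an estimated correlation). Per3 was at least 5.43-fold higher at 24 months, and Tef rose from -1.27 ± 0.19 to 0.53 ± 0.30 (5.97e-05). The smallest log2 change of Per3 over the alternatives was 1.27. Of 30 genes of fatty acid oxidation 5 rose (5 in the list alone), median 0.53 (adjusted p = 1.49e-05, 0.590 with an estimated correlation): Acaa2, Cpt2, Decr1, Ehhadh and Ppara. Cpt2, which imports long-chain fatty acids into mitochondria, rose from 3.83 ± 0.09 to 5.24 ± 0.56 (0.0019). The score of this list was 0.81 on 24-month array 1 but -0.47 on array 4, within the range of the 3-month arrays (-0.58 to -0.44). Of 9 class II genes 5 rose and Ifi30 fell (6 and 1 in the list alone), median 2.40 (adjusted p = 0.000109, 0.590 with an estimated correlation). RT1-Bb rose from 2.02 ± 0.11 to 4.69 ± 0.74 and RT1-Db1 from 0.82 ± 0.03 to 3.35 ± 1.03, and whether probes of 1 RT1 gene also read another was not tested. Of 20 heat shock genes 5 rose (6 in the list alone), median 0.32 (adjusted p = 0.000258, 0.590 with an estimated correlation): Chordc1, Dnajb1, Hsf1, Hspa8 and Hspb8. The heat shock score of 24-month array 3 (-0.14) lay within the range at 3 months (-0.19 to -0.06). Those of arrays 1, 2 and 4 (0.32, 0.52 and -0.02) lay above it. Of 26 genes of cholesterol synthesis 4 rose, among them Hsd17b7, Mvk and Nsdhl (4 in the list alone), median 0.37 (adjusted p = 0.00843, 0.746 with an estimated correlation). Mvk, the mevalonate kinase, rose from 0.98 ± 0.16 to 1.87 ± 0.51 (0.0291). The cholesterol scores of 24-month arrays 1 and 4 (-0.16 and -0.01) lay within the range at 3 months (-0.23 to 0.01), and those of arrays 2 and 3 (0.61 and 0.64) above it. Of 23 T and NK cell genes 6 rose, among them Cd2, Cd6, Klrd1, Lat and Zap70, and Gzma, Gzmb and Klrb1a fell (8 and 3 in the list alone), median 0.77 (adjusted p = 0.00972, 0.746 with an estimated correlation). The T and NK cell score of 24-month array 1 (0.51) lay within the range of the 3-month arrays (0.46 to 0.60) and that of array 4 (0.41) below it. Those of arrays 2 and 3 (1.64 and 1.80) lay above it. Gzma, a granule protease of cytotoxic cells, fell from 2.81 ± 0.16 to 1.03 ± 0.25 (0.000136).

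The other 21 lists did not pass by camera, and by fry 1 of them did, the GH, IGF and insulin axis (adjusted p = 0.0067). Of macrophage and Kupffer cell genes, Adgre1, Cd163, Marco and Vsig4 rose and Timd4 fell (median 0.15, adjusted p = 0.111), and Vsig4 was 4.07-fold higher. Early response genes had a median of -0.36 (0.111), pancreas genes -0.73 (0.153), ER stress genes -0.32 (0.172), genes of the GH, IGF and insulin axis -0.31 (0.208), B and plasma cell genes 0.37 (0.25) and cholangiocyte genes 0.18 (0.314). Female-biased genes had a median of 0.02 (0.554), oxidative phosphorylation 0.03 (0.554), endothelial genes 0.11 (0.577), autophagy 0.00 (0.577), hepatocyte genes -0.13 (0.765) and fatty acid synthesis -0.19 (0.808). Lysosome (-0.00), oxidative stress defence (-0.11) and senescence-associated genes (-0.04) each had an adjusted p of 0.966. In the latter list Il1b and Mmp12 rose, and Cdkn2a and Timp1 were among 3 that fell. Sign differed between median, mean and test for 5 lists: bile acid genes (-0.12, 0.01, lower, 0.808), glucose metabolism (0.07, -0.07, higher, 0.808), xenobiotic metabolism (-0.07, 0.23, higher, 0.27), erythroid genes (-0.32, -0.07, higher, 0.966) and adipose genes (-0.38, -0.07, higher, 0.765).

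Leaving out 1 array ended calls of some list members named for 24 against 3 months. The array was 3-month array 1 for Col1a2 (adjusted p = 0.0586), 3-month array 3 for Camp (0.055), Mpo (0.0771) and Chordc1 (0.0539), and 3-month arrays 1 or 2 for Pdgfrb (up to 0.059), Rup2 (0.0673) and Cyp2c13 (0.0686). Any 3-month array did so for Ppara (up to 0.0973), and several arrays of both ages for Ehhadh (0.113), Hpx (0.116), C3 (0.176), Spink3 (0.12), Timp1 (0.118), Hsd17b7 (0.122), Mvk (0.117), Nsdhl (0.144), Hsf1 (0.122) and Dnajb1 (0.128). For Cdkn2a it was 3-month array 1 or 3 (0.056). With normexp background correction the log2 changes of Klrb1a (0.0019) and Mpo (0.14) reversed. Scan session 1, the only batch that held both ages, held all of their arrays. A fit within it gave the same log2 changes with another estimate of the spread (3831 genes passed), so it did not test for a batch effect. With slide as a random block 310 passed, and 93 of the 115 named calls ended. All 115 kept their sign, with a median size of 1.51 on the log2 scale before and after, while the median SE rose from 0.263 to 0.456. Among the 93, H19 went from 4.19 ± 0.76 (SE) to 4.45 ± 1.09 (adjusted p = 0.0646) and Usp2 from 3.02 ± 0.55 to 2.65 ± 0.80 (0.138). Cd74 went from 2.93 ± 0.45 to 2.85 ± 0.88 (0.145) and Bmal1 from -3.36 ± 0.73 to -3.38 ± 1.35 (0.287). Slide and age cannot be told apart here, since no slide held both ages.

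**Figure D1:**
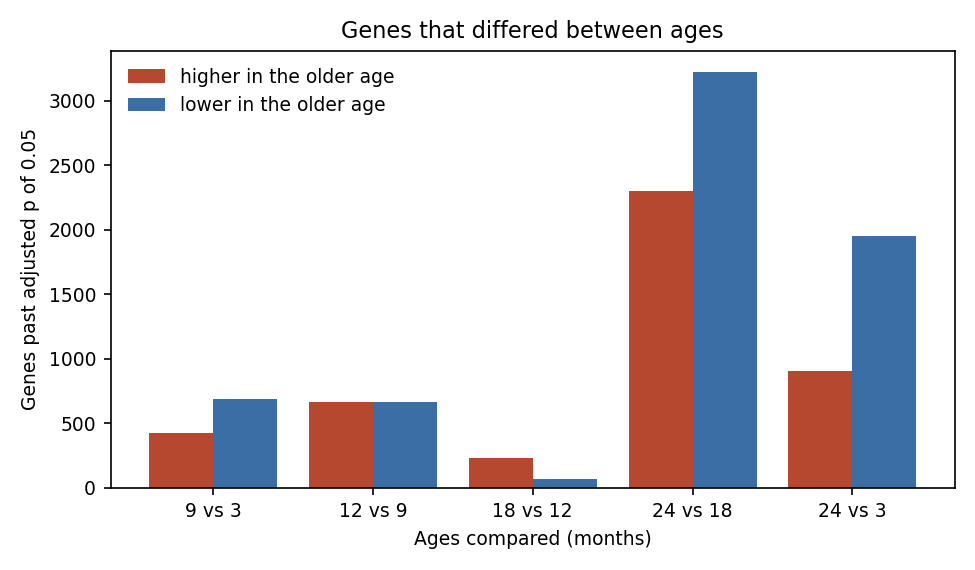
Number of genes past an adjusted p of 0.05 (y axis) for 5 comparisons of ages in months (x axis), split into genes higher and lower in the older age. The comparison of 24 with 18 months had the most, 2297 higher and 3226 lower.

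The comparison of 9 with 3 months asked which transcripts differed at the first step in age. At 9 months the liver held less mRNA of 11 of 23 T and NK cell genes, 11 of 34 interferon-induced genes, 3 of 10 neutrophil genes and 6 of 19 early response genes. It held more mRNA of 5 of 22 genes of fatty acid synthesis. As lists, these did not pass with an estimated correlation (adjusted p = 0.248 for the lower and 0.344 for the higher list). The costimulatory receptor Tnfrsf9 fell from 1.13 ± 0.13 (SD, n = 3) to -3.17 ± 0.56 (SD, n = 3), 19.6-fold lower (adjusted p = 8.28e-05), and the lipase Pnpla5 rose from -1.43 ± 0.30 to 4.12 ± 0.49, 46.8-fold higher (0.00503). By limma 1110 genes differed, 424 higher and 686 lower at 9 months.

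Pnpla3, a lipid droplet protein, was 69.2-fold higher at 9 months (adjusted p = 0.0119), Gimd1 14.9-fold (0.00174), the desaturase Scd2 15.0-fold (0.0478) and Vxn 9.74-fold (0.0174). The neutrophil chemokine Cxcl1 was 46.5-fold lower (0.00521), the IGF-binding protein Igfbp1 19.0-fold (0.000148), the neutrophil protein S100a9 16-fold (0.022) and Ifit1bl 12.9-fold (0.000107). Calls were lost without 3-month array 1 or 9-month array 3 for Pnpla3 (up to 0.0517), without 3-month arrays 2 or 3 or 9-month arrays 2 or 3 for Vxn (0.0857), and without any of the 6 arrays for Scd2 (0.149) and S100a9 (0.0911).

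Of the 33 lists 17 passed between 9 and 3 months, 5 higher and 12 lower, and none passed with an estimated correlation. Of 23 T and NK cell genes 11 fell (19 in the list alone), with a median of -1.58 (adjusted p = 1.8e-17, 0.248 with an estimated correlation). Gzmb fell from -0.30 ± 0.23 to -2.77 ± 0.20 and Gzmk from 0.62 ± 0.10 to -1.90 ± 0.20. Of 34 interferon-induced genes 11 fell (21 in the list alone), median -0.87 (7.8e-16, 0.248 with an estimated correlation), among them Irf7 (6.33 ± 0.02 to 3.62 ± 0.09) and Gbp2 (4.38-fold). Of 10 neutrophil genes Camp, Fcnb and S100a9 fell (6 in the list alone), median -3.35 (7.61e-07, 0.248 with an estimated correlation), and Camp was at least 10.3-fold lower. The smallest log2 change of Camp over the alternatives was -1.32. Of 19 early response genes 6 fell and Jund rose (8 and 1 in the list alone), median -0.57 (1.08e-06, 0.248 with an estimated correlation), with Gadd45b 5.23-fold lower and Junb 5.64-fold lower. Of 24 macrophage and Kupffer cell genes 7 fell and Cd163 and Vsig4 rose (11 and 3 in the list alone), median -0.53 (1.78e-05, 0.453 with an estimated correlation), with Lyz2 4.93-fold lower. Of 22 genes of fatty acid synthesis Fads1, Fads2, Me1, Pklr and Pnpla3 rose (11 in the list alone, where 1 fell), median 0.97 (4.95e-07, 0.344 with an estimated correlation). Me1, which supplies NADPH, rose from 2.48 ± 0.06 to 3.67 ± 0.21.

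Cell cycle genes were lower as a list between 9 and 3 months without a call for a member (median -0.73, adjusted p = 2.74e-07, 0.344 with an estimated correlation). Oxidative phosphorylation was higher in the same way (0.28, 2.21e-06, 0.512). Col3a1, Timp1 and Vim fell in the matrix list (-0.31, 2.13e-05, 0.248), and Hpx, Il1rn and Orm1 in the acute phase list (-0.19, 0.0002, 0.248). Nsdhl and Sc5d were among 3 genes that rose in the cholesterol list (0.40, 0.00044, 0.512), Cpt2 in fatty acid oxidation (0.35, 0.00391, 0.597) and Hnf4a in the hepatocyte list (0.20, 0.00769, 0.615). Sdf2l1 fell and Atf4 rose in the ER stress list (-0.28, 0.00283, 0.344), and Abcg1 and Sult2a6 fell in the female-biased list (-0.63, 0.00405, 0.344). B and plasma cell genes were lower with 0 calls (-0.77, 0.0205, 0.361). Cxcl1, Plau and Timp1 were among 4 genes that fell in the senescence-associated list (-0.30, 0.0367, 0.453), which did not pass with scan session as a block (0.0942). Each bracket gives the median, the adjusted p and that with an estimated correlation. The other 16 lists did not pass.

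Single arrays also ended calls of list members at this step. Calls of Timp1 (up to 0.0595) and Vim (0.0623) were lost without 3-month arrays 1 or 3 or 9-month array 3. Those of Cpt2 (0.149), Sc5d (0.171), Hnf4a (0.103), Hpx (0.138) and Orm1 (0.0943) were lost without any of the 6 arrays. Fads1 (0.0714), Fads2 (0.0678), Sdf2l1 (0.0872), Abcg1 (0.058) and Sult2a6 (0.0616) were lost without 2 to 5 of the 6, at least 1 of 3 months each time. Within slide 1, which held 3 arrays of 3 months and 1 of 9 months, 1891 genes passed between 9 and 3 months, the lone 9-month array being assumed to vary like the other groups. Leaving out 1 array gave from 474 genes (without 3-month array 3) to 650 (without 9-month array 2), against 1110.

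The comparison of 12 with 9 months covered the next step. Clock genes separated these ages in both directions, 10 of 18 higher and 4 lower at 12 months. Lower too were 7 of 26 genes of cholesterol synthesis and 6 of 22 of fatty acid synthesis, lists that did not pass with an estimated correlation (adjusted p = 0.805, and 0.715 for the clock list) or with scan session as a block (0.0793 and 0.0756). Dbp rose from -0.36 ± 0.22 (SD, n = 3) to 5.41 ± 0.11 (SD, n = 3), 54.4-fold (adjusted p = 4.82e-05), while Bmal1 fell from 2.24 ± 0.03 to -2.34 ± 1.01, 23.9-fold (0.00633). Here too the unstated hour of tissue collection cannot be told apart from age for clock genes, and was not tested for others. By limma 1337 genes differed, 669 higher and 668 lower at 12 months.

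Bhlhe41 was 28.2-fold higher at 12 months (adjusted p = 6.81e-05), the steroid enzyme Hsd17b2 20.9-fold (0.0137), the uridine phosphorylase Upp2 11.7-fold (0.00218) and Usp2 11.5-fold (0.00581). The growth hormone signal inhibitor Socs2 was 15.3-fold lower (0.0163), the insulin receptor substrate Irs3 11.8-fold (0.00859), the clock factor Npas2 11-fold (0.037) and the choline kinase Chka 9.25-fold (0.00065). The call of Hsd17b2 was lost without 9-month array 2 (0.0511), that of Socs2 without 9-month arrays 1 or 2 or 12-month array 4 (up to 0.0598), and that of Npas2 without any of the 6 arrays (0.101). Within scan day 1, Irs3 (0.0723) and Npas2 (0.0775) did not pass.

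Of the 33 lists 9 passed between 12 and 9 months, 3 higher and 6 lower, and none with an estimated correlation. Of 18 clock genes 10 rose and Bmal1, Clock, Nfil3 and Npas2 fell (11 and 4 in the list alone), median 1.41 (adjusted p = 0.00021, 0.715 with an estimated correlation). Tef rose from -1.64 ± 0.18 to 0.64 ± 0.06, and Per3 was at least 5.14-fold higher. The smallest log2 change of Per3 over the alternatives was 1.01. Of 26 genes of cholesterol synthesis 7 fell (12 in the list alone), median -0.72 (6.1e-06, 0.805 with an estimated correlation), with Pmvk 2.86-fold lower. Of 22 genes of fatty acid synthesis 6 fell (10 in the list alone), median -0.81 (8.72e-05, 0.805 with an estimated correlation), with Me1 2.53-fold and Fads1 2.92-fold lower. Of 19 early response genes 6 rose and Jund fell (6 and 1 in the list alone), median 0.40 (0.0409, 0.805 with an estimated correlation), with Egr1 7.05-fold and Zfp36 3.38-fold higher. Of 31 cell cycle genes 6 fell and Ccne1 rose (7 and 1 in the list alone), median -0.44 (0.00174, 0.805 with an estimated correlation). Atp5f1c, Cox4i1, Cyc1 and Ndufs4 fell in the oxidative phosphorylation list (4 in the list alone), median -0.20 (0.00021, 0.805 with an estimated correlation). Cd6 and Lat rose in the T and NK cell list (8 in the list alone), median 1.10 (0.000482, 0.805 with an estimated correlation). Ifi27, Igtp, Irgm and Rig1 fell in the interferon list (4 in the list alone), median -0.29 (0.0409, 0.805 with an estimated correlation). Epcam and Slc4a2 fell in the cholangiocyte list (3 in the list alone), median -0.40 (0.0432, 0.805 with an estimated correlation).

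Calls of the 4 oxidative phosphorylation members (adjusted p up to 0.181), Cd6 (0.119), Lat (0.129), Ifi27 (0.11), Igtp (0.12) and Slc4a2 (0.0963) were lost without any 9-month array. Without 12-month array 4 these were lost too, except Atp5f1c, and without array 2 the oxidative phosphorylation members and Ifi27, and without array 3 Cd6 and Lat. Those of Irgm (0.0522) and Rig1 (0.065) were lost without 9-month arrays 1 or 3, and that of Epcam (0.0641) without 9-month arrays 1 or 2 or 12-month array 4. The 9-month arrays entered both this comparison and that of 9 with 3 months, so opposite changes of fatty acid synthesis and early response genes in the 2 share the same 9-month values. With scan session as a block, which for this comparison equals scan day 1 alone, 4370 genes passed. That fit sets 1 array of 12 months, replicate 2, which stood apart from its group, against 3 of 9 months, and assumes that the lone array varies like the other groups. In it the clock (0.0314), cell cycle (0.0244) and oxidative phosphorylation lists (3.47e-05) passed. Cholesterol synthesis (0.0793), fatty acid synthesis (0.0756), T and NK cell genes (0.905), interferon (0.0737), early response (0.0756) and cholangiocyte genes (0.263) did not.

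**Figure D2:**
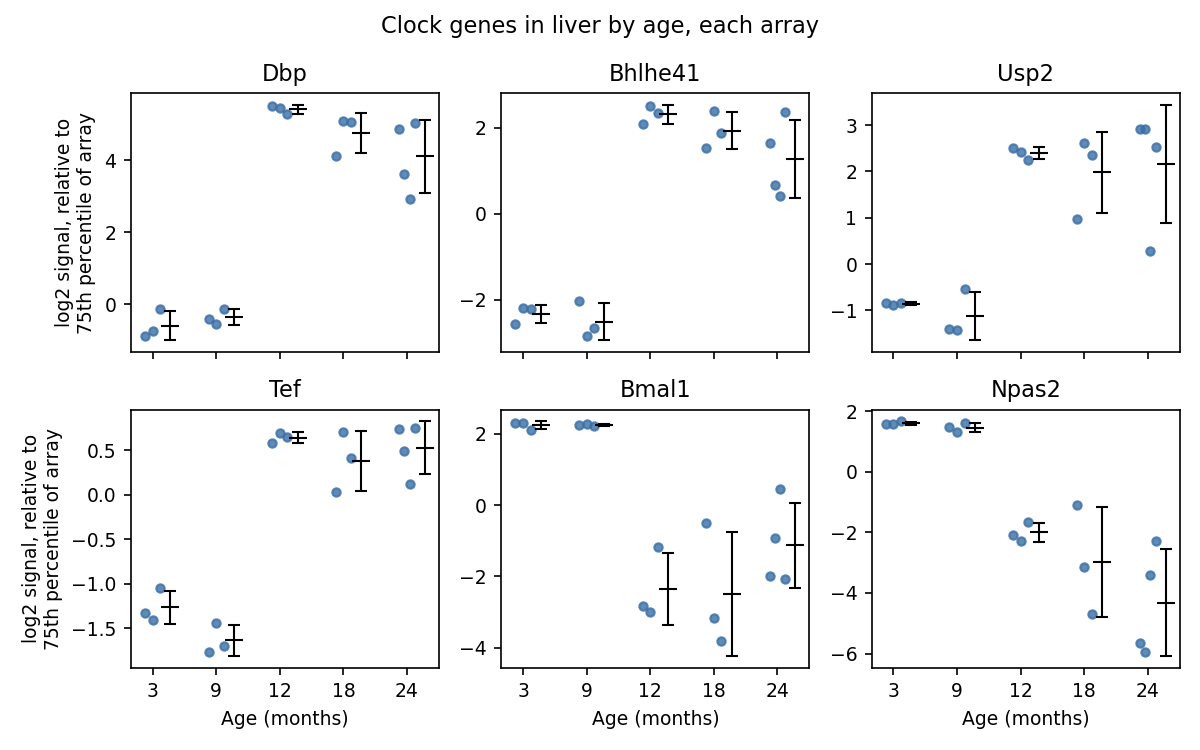
Log2 signal relative to the 75th percentile of the array (y axis) of 6 clock genes by age in months (x axis), with a point per array and bars for the mean ± SD. Dbp had a mean of -0.36 at 9 months and 5.41 at 12 months, and Bmal1 one of 2.24 and -2.34.

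The comparison of 18 with 12 months gave the fewest differences: by limma 295 genes, 230 higher and 65 lower at 18 months. With slide as a random block 0 passed, and the calls of all 16 chosen genes ended. These kept their sign, with a median size of 1.40 on the log2 scale before and 1.37 after, while the median SE rose from 0.256 to 0.465. The membrane protein gene Tmem52 rose from 0.95 ± 0.37 (SD, n = 3) to 2.99 ± 0.31 (SD, n = 3), 4.10-fold (adjusted p = 0.00234). Ergic2, of the early secretory pathway, was 4.43-fold higher (0.00595), and the collagen gene Col3a1 fell from 3.37 ± 0.12 to 2.47 ± 0.22, 1.87-fold (0.00699). With the slide block their adjusted p was 0.159, 0.135 and 0.549.

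The adhesion gene Cdh13 was 6.34-fold higher at 18 months (adjusted p = 0.0289), the copper importer Slc31a1 4.60-fold (0.0106) and Fbxo17 3.31-fold (0.0289). Tenm2 was 2.50-fold lower (0.0336), the endothelin receptor Ednra 2.19-fold (0.0366), the magnesium channel Trpm6 2.02-fold (0.038) and Pitpnc1 1.90-fold (0.0462). Calls were lost without any 18-month array for Cdh13 (up to 0.124), Fbxo17 (0.127), Tenm2 (0.123), Ednra (0.145) and Trpm6 (0.148), and without 18-month arrays 1 or 3 for Slc31a1 (0.0535). That of Pitpnc1 was lost without 18-month arrays 1 or 4 or 12-month arrays 2 or 3 (0.182). Leaving out 12-month arrays also ended calls: array 2 for Cdh13, Fbxo17, Tenm2 and Trpm6, and array 4 for Cdh13, Tenm2, Ednra and Trpm6.

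Of the 33 lists 5 passed between 18 and 12 months, each with an adjusted p of 0.934 with an estimated correlation. The number was 1 without 12-month array 3, 2 without 12-month array 4 or 18-month array 3, 3 without 18-month array 4, and 11 with normexp. Xenobiotic metabolism was higher (median 0.41, adjusted p = 0.00136) with the glucuronosyltransferase Ugt2b1 called (2 in the list alone), a call lost without 18-month array 1 (0.059). Fatty acid oxidation (0.31, 0.0221) and heat shock genes (0.32, 0.0221) were higher and T and NK cell genes lower (-0.84, 0.0221), with 0 members called for each (0 in the list alone). The T and NK cell score of 12-month array 2 (-0.83) lay within the range at 18 months (-0.90 to -0.66). Those of 12-month arrays 3 and 4 (0.28 and -0.01) lay above it. The matrix list was lower (-0.30, 0.0263), with Col3a1 and Mmp2 called (8 in the list alone). The call of Mmp2 was lost without 12-month array 2 or any 18-month array (0.165). Within scan day 3, with 2 arrays of 12 months and 3 of 18 months, 174 genes passed, and 6 of the 16 chosen genes: Slc31a1, Ergic2, Tmem52, Ednra, Ugt2b1 and Col3a1. Fatty acid oxidation did not pass there (0.156).

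The comparison of 24 with 18 months asked which transcripts differed at the last step in age. At 24 months the liver held more mRNA of T and NK cell genes, MHC class II genes and macrophage genes, with 18 of 23, 7 of 9 and 14 of 24 members higher. As lists, these did not pass with an estimated correlation (adjusted p = 0.752 each). The T cell chemokine Ccl5 rose from 2.03 ± 0.73 (SD, n = 3) to 5.43 ± 0.96 (SD, n = 4), 10.6-fold (adjusted p = 0.000406). Cd74 rose from 2.87 ± 0.15 to 5.86 ± 0.73, 7.97-fold (0.000319). By limma 5523 genes differed, 2297 higher and 3226 lower at 24 months, a balance that turned over among probes above background on all arrays (1932 higher and 1776 lower).

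No batch held both 18 and 24 months, so a fit with scan session as a block was set beside these values. It is bridged by the 12-month arrays alone, of which 1, replicate 2, was in the session of the 24-month arrays. That array stood apart from its group, and the fit assumes that it varies like the other groups. On it the T and NK cell score was -0.83, against 0.28 and -0.01 on the other 12-month arrays. This gap enlarges the change that the block gives for these genes. Nkg7, of cytotoxic granules, was 8.95-fold higher (adjusted p = 0.000145, log2 change 4.57 and 0.0034 with the block) and the chemokine Ccl4 8.51-fold (0.000536, 4.56 and 0.00763). For Ccl5 and Cd74 the block gave 5.38 (0.00319) and 4.09 (0.00981), but with slide as a random block their calls ended (3.42 ± 0.93 (SE), 0.054, and 3.00 ± 1.03, 0.138, from 3.40 ± 0.53 and 2.99 ± 0.45). The mesothelial gene Msln was 7.58-fold higher (0.0113), but not with the block (2.13, 0.349) or without 18-month array 4 (0.0561). Rps26 was 19.4-fold lower (1.01e-05, -4.60 and 0.00587) and Slc31a1 18.4-fold (3.68e-06, -2.29 and 0.00081). Obp3 was 24.5-fold lower (0.00494), Mup4 14.5-fold (0.00602) and the taurine enzyme Csad 9.84-fold (0.00025), but none passed with the block (-1.60 and 0.578, -2.02 and 0.437, -2.10 and 0.126). Whether the probes of Obp3 and Mup4 read other genes of their family was not tested.

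Of the 33 lists 10 passed between 24 and 18 months, 8 higher and 2 lower, and none with an estimated correlation. With normexp 18 passed, 9 higher and 9 lower. Not all of the 8 higher lists were also higher than at 3 months. Mean scores at 3 and 24 months were 0.96 and 0.10 for interferon and 0.39 and 0.02 for matrix genes. They were 0.91 and -0.08 for cell cycle and 0.28 and 0.25 for senescence-associated genes. The T and NK cell, class II, macrophage and cholesterol scores were higher at 24 than at 3 months. Of 23 T and NK cell genes 18 rose (18 in the list alone), median 2.17 (adjusted p = 4.97e-10, 0.752 with an estimated correlation), and the block gave 3.41 (9.49e-14). Gzmm rose from -0.21 ± 0.09 to 2.66 ± 0.73 and Prf1, the pore-forming perforin, from -0.69 ± 0.26 to 1.11 ± 0.51 (block 4.50, 0.00114, and 2.04, 0.0148). Of 9 class II genes 7 rose (9 in the list alone), median 1.94 (7.78e-05, 0.752 with an estimated correlation), and the block gave 3.32 (7.54e-05), with RT1-Bb 6.81-fold higher (block 3.79, 0.0158). Of 24 macrophage and Kupffer cell genes 14 rose (21 in the list alone), median 0.79 (1.7e-07, 0.752 with an estimated correlation), and the block gave 0.83 (4.81e-05), with Adgre1 2.21-fold higher (block 0.97, 0.049). Of 34 interferon-induced genes 10 rose (11 in the list alone), median 0.45 (0.0047, 0.886 with an estimated correlation), and the block gave 0.43 (0.00124), with Gbp2 4.37-fold higher (block 2.30, 0.0396). Of 28 matrix genes 11 rose and Col1a1 and Col4a1 fell (13 and 2 in the list alone), median 0.49 (0.00706, 0.752 with an estimated correlation, 0.0149 with the block). Mmp2, a gelatinase, was 2.67-fold higher (block 1.29, 0.0284).

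Of 31 cell cycle genes Foxm1, Mcm3, Mcm6 and Prc1 rose and Cdc20 and Rrm2 fell between 18 and 24 months (3 and 2 in the list alone), median 0.68 (adjusted p = 0.0264, 0.954 with an estimated correlation, 0.0149 with the block). The cell cycle scores of 24-month arrays 1 and 4 (-0.52 and -0.44) lay within the range at 18 months (-0.77 to -0.38). Those of arrays 2 and 3 (0.85 and -0.19) lay above it. Prc1 lay above background on 1 of the 7 arrays. Foxm1 had a log2 change of -0.33 with the block, and its call was lost without any of 6 single arrays of these ages, all but 24-month array 1 (up to 0.0901). Of 26 genes of cholesterol synthesis 10 rose and 2 fell (13 and 2 in the list alone), median 0.59 (0.00426, 0.886 with an estimated correlation). Of 22 senescence-associated genes 7 rose and Cdkn2a and Cdkn2b fell (7 and 2 in the list alone), median 0.43 (0.0264, 0.752 with an estimated correlation). Of 10 pancreas genes 7 fell and Cpb1 rose (7 and 2 in the list alone), median -1.46 (0.0493, 0.752 with an estimated correlation). Cyp2c13, Dhrs7, Mup4 and Obp3 fell in the male-biased list (4 in the list alone), median -0.52 (0.013, 0.886 with an estimated correlation). The block ended the calls of these last 4 lists, with an adjusted p of 0.43, 0.0886, 0.129 and 0.852 in that order. Calls of Cyp2c13 (0.131) and Dhrs7 (0.113) were lost without any 18-month array or 24-month arrays 2 or 3, and that of Cyp2c13 also without 24-month array 1. Neither passed with the block (0.439 and 0.257). With the block 2808 genes passed, 1266 of them among the 5523, and of 98 chosen genes 93 kept their sign and 24 passed. With slide as a random block 978 genes passed, 61 higher and 917 lower, and 87 of the 98 ended. All 98 kept their sign, with a median size of 1.24 on the log2 scale before and 1.26 after, while the median SE rose from 0.234 to 0.408.

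**Figure D3:**
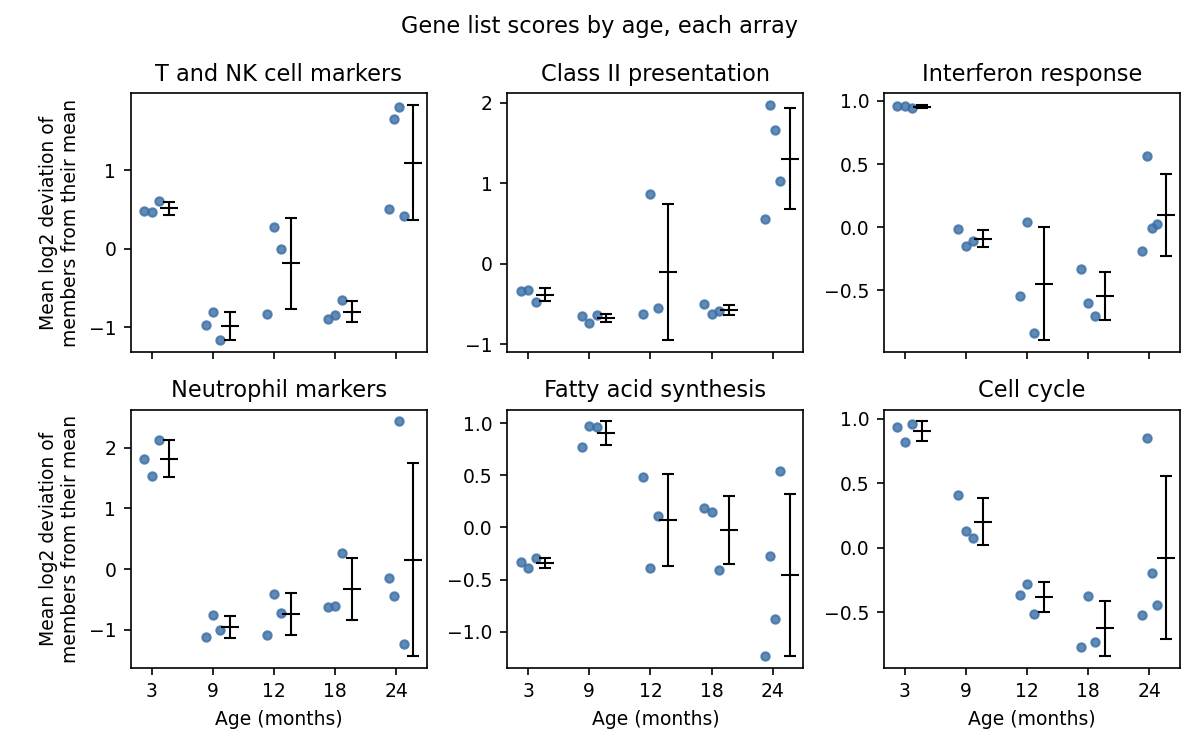
Mean log2 deviation of the members of 6 gene lists from their means over all arrays (y axis) by age in months (x axis), with a point per array and bars for the mean ± SD. The T and NK cell scores of the 24-month arrays were 0.51, 1.64, 1.80 and 0.41, against 0.46 to 0.60 at 3 months.

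A linear trend over the 5 ages asked which genes had a slope with age, which does not show that a change was steady. For clock genes such as Per2 and Dbp, the unstated hour of tissue collection cannot be told apart from age. Fbp2 rose by 4.16 on the log2 scale over 21 months (adjusted p = 4.92e-06), H19 by 4.01 (0.0055), Per2 by 3.11 (0.00547) and Cdh13 by 2.82 (0.0158). Gadd45g fell by 3.05 (0.00138), the glutathione transferase Gstp3 by 2.51 (0.00539), the transporter Slc45a3 by 2.38 (0.000896) and the kynurenine enzyme Kynu by 2.33 (0.00241). These 8 kept their calls without each array in turn, and the other 12 genes with the largest slopes did not. With slide as a random block the calls of 18 of the 20 ended, and those of Fbp2 (0.00145) and Slc45a3 (0.0464) stayed. All 20 kept their sign, and the median SE of a slope rose from 0.033 to 0.042 per month. Among the 12 were Dbp (5.13, 0.0256), lost without any 3-month array or 24-month array 1 (up to 0.0725), and Cd74 (2.81, 0.0271), lost without any 24-month array (up to 0.071). By limma 1250 genes had a trend, 367 rising and 883 falling. An F test of any age difference called 8031 genes.

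Of the 33 lists 10 passed for the trend, 6 higher and 4 lower with age, and 54 of 100 splits gave as many. Medians over 21 months were 0.58 for fatty acid oxidation (adjusted p = 1.5e-06, 0.614 with an estimated correlation), with Cpt2, Decr1 and Ppara called, and 0.40 for heat shock genes (4.68e-05, 0.614), with Chordc1, Hsp90aa1 and Hspb8 called. Class II genes had 2.30 (8.25e-05, 0.614) with 5 of 9 called, clock genes 0.97 (0.00104, 0.563) with 7 of 18 rising and Npas2 falling, T and NK cell genes 0.98 (0.00147, 0.802) with 0 called and mean scores of 0.51, -0.98, -0.19, -0.80 and 1.09 at the 5 ages, and Kupffer cell genes 0.15 (0.0151, 0.802) with Cd163, Marco and Vsig4 called. Falling lists were cell cycle (-0.79, 8.25e-05, 0.788) with Cdc20 and Rrm2 called, interferon (-0.64, 0.00078, 0.802) with 5 of 34 called, male-biased genes (-0.75, 0.000814, 0.773) with Cyp2c13, Rup2 and Sult1c3 called, and matrix (-0.33, 0.0442, 0.802) with 5 of 28 called. Adjusted over the list alone, 7 members passed for fatty acid oxidation, 4 for heat shock, 5 for class II, 14 for the clock, 0 for T and NK cells, 3 for Kupffer cells, 16 for the cell cycle, 6 for interferon, 9 for male-biased and 6 for matrix genes. The trend was called for 5021 genes without the 24-month arrays and 603 without the 3-month arrays, and for 46 with slide as a random block.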

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

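The tests in this part were chosen before the data were examined, and the genes tested include some chosen after. Among the 4 arrays of 24 months, 1 array lay far from the other 3 in 10 of 243 values tested, where chance gives about 1 in 20. The clock-controlled protease Usp2 was at 0.28 on 24-month array 3, against 2.52 to 2.93 on the others. On the same array the glutathione transferases Gstp3 (4.20, others 5.95 to 6.18) and Gsta1 (7.75, others 8.36 to 8.46) and the insulin receptor substrate Irs1 (-2.26, others -1.90 to -1.86) were low. On it the defensin gene Defa5 was high (3.12), as was the acute phase score (0.68, others -0.03 to -0.11). On 24-month array 4 the mesothelial gene Msln (0.75, others -0.14 to -0.17) and the bile acid transporter Slco1b2 (5.76, others 5.17 to 5.11) were high. On 24-month array 1 the transporter Abcb1a (-3.63) was high, and on array 2 the interferon factor Irf9 (0.95, others 0.40 to 0.30). For Defa5 and Abcb1a the other 3 arrays lay below background, whose limits run from -4.55 to -3.75, so noise sets their distances there and no gap is given. No explanation was weighed for these values.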

How the results depend on the processing

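Scan session as a block, fits within a batch and the joint omission of 24-month arrays 3 and 4 were chosen after seeing the data; the other alternatives were set beforehand. Signal over background limits what the arrays show of dim genes. Where no cause is named below, the cause was not tested. Quantile normalization and the series table gave 2700 and 2697 genes for 24 against 3 months, near the 2858 of the main choice. Normexp called 482 genes for 24 against 3 months, 339 for 9 against 3, 166 for 12 against 9, 37 for 18 against 12, 968 for 24 against 18, 1609 for any age difference and 184 for the trend. Lists with normexp were 17 for 24 against 3 months (3 higher, 14 lower), 11 for 18 against 12, 18 for 24 against 18 (9 and 9) and 18 for the trend (4 and 14). Normexp reversed the log2 change of Klrb1a (0.0019), Mpo (0.14) and Prss2 (0.077) for 24 against 3 months, and of Abcb1a (0.032), Atg9a (0.092), Cd79a (0.058), Bicc1 (0.15) and Egr3 (0.090) for 24 against 18. Without a filter 12 against 9 months gave 682. With probes above background on all arrays 24 against 3 months gave 1899 and the trend 675, with fewer genes tested. There 24 against 18 months gave 3708, 1932 higher and 1776 lower, and Wnt2 for 24 against 18 months reversed (0.19).

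Slide as a random block gave 310 for 24 against 3 months, 2050 for 9 against 3, 4825 for 12 against 9, 978 for 24 against 18 (61 higher, 917 lower), 4823 for any difference and 46 for the trend. For 18 against 12 it gave 0 by limma, where 3909 genes had an unadjusted p under 0.05 without the block. Slide as a fixed block over 3, 9 and 12 months gave 2283 and 6583 for the first 2 steps. Replicate number as a block gave 365 for 12 against 9 months, 97 for 18 against 12 and 668 for the trend, and these numbers do not pair the samples (correlations across genes of deviations from the age mean, -0.30 to 0.07). Fits on the compared ages alone gave 4125, 218 and 2 for the first 3 steps. The trend gave 603 without the 3-month arrays and 5021 without the 24-month arrays. A fold of at least 2 left 1557, 653, 579 and 2880 for 24 against 3, 9 against 3, 12 against 9 and 24 against 18 months, by construction. With an estimated correlation 0 lists passed for 24 against 3 months and 0 for the trend, and by fry 7 and 3, against 12 and 10 by camera.

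Scan session as a block gave 4370 for 12 against 9 months, 174 for 18 against 12, 2808 for 24 against 18 and 2353 for the trend. For 12 against 9 and 18 against 12 this equals the fits within scan days 1 and 3. It reversed the log2 change for 24 against 18 months of Igfbp1 (-0.41), Atg9a (0.46), Foxm1 (-0.33), Egfl7 (-0.45) and Jund (-0.053). Within slide 1, 9 against 3 months gave 1891, and within slide 2, 12 against 9 gave 5822. Without 24-month arrays 3 and 4 together, 24 against 3 months gave 3223 and 24 against 18 gave 5439.

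Leaving out 1 array gave 1572 (3-month array 2) to 3362 for 24 against 3 months, with 1604 and 1699 without 3-month arrays 1 and 3. It gave 474 to 650 for 9 against 3, where each of the 6 arrays moved the count. For 12 against 9 months it gave 485 (9-month array 1) to 2148 (12-month array 2), with 537, 510 and 764 without 9-month arrays 2 and 3 and 12-month array 4. For 18 against 12 months it gave 82 (18-month array 1) to 721 (12-month array 3), with 98, 92, 174 and 451 without 18-month arrays 3 and 4 and 12-month arrays 2 and 4. The range was 3891 to 6169 for 24 against 18 months, 6279 to 9751 for any difference, and 647 (3-month array 1) to 1664 for the trend, with 709, 808 and 703 without 3-month arrays 2 and 3 and 24-month array 1. Lists ranged from 9 to 13 for 24 against 3 months, 8 to 15 for the trend, 16 to 18 for 9 against 3, 5 (12-month array 2) to 8 for 12 against 9, 1 to 5 for 18 against 12 and 8 to 11 for 24 against 18.

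Of 397 calls of the genes chosen for the text, 66 were lost under none of the alternatives run. Over 7757 values of these genes, 1783 lost their call, 31 gained one and 14 reversed. In every omission of 1 array, 79 of 115 calls stayed for 24 against 3 months, 34 of 72 for 9 against 3, 30 of 76 for 12 against 9, 3 of 16 for 18 against 12, 67 of 98 for 24 against 18 and 8 of 20 for the trend.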

Other observations

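The tests of the clock and immune patterns and that of the 75th percentile shift were chosen after the results were seen, and those on other splits of the arrays and on dim probes before.

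Igfbp1, Cyp7a1, Pck1 and Mt1, picked after their values were seen, fell and rose again over the first 2 steps, which share the 9-month arrays. None of the 4 lists that hold them passed by camera at 9 against 3 months (adjusted p from 0.298 to 0.851) or at 12 against 9 (from 0.0834 to 0.767), where by fry that of Mt1 did (0.0382). The hepatic stress protein Igfbp1 had a log2 signal of 5.30 ± 0.09 (SD, n = 3) at 3 months, 1.05 ± 0.30 at 9 months and 4.20 ± 1.02 at 12 months. Cyp7a1, the first enzyme of bile acid synthesis, had 1.97 ± 0.18, -0.28 ± 0.64 and 3.13 ± 0.73. The fall of Cyp7a1 was lost without any 3-month array or 9-month arrays 1 or 2 (adjusted p up to 0.0805). The gluconeogenic enzyme Pck1 had 6.70 ± 0.14, 5.93 ± 0.23 and 7.10 ± 0.15, its fall being lost without any of the 6 arrays (0.149). The metal-binding Mt1 had 9.46 ± 0.10, 7.51 ± 0.66 and 9.31 ± 0.62, its fall being lost without any 3-month array or 9-month arrays 2 or 3 (0.0981), and its rise without those 9-month arrays or 12-month arrays 2 or 4 (0.112).

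Some metabolic genes outside the called lists differed between 3 and 24 months. The glycogen synthase Gys2 rose from 6.29 ± 0.03 to 7.40 ± 0.19 (SD, n = 4) and the glycogen phosphorylase Pygl fell from 4.02 ± 0.02 to 2.77 ± 0.46. The glucokinase regulator Gckr was 3.62-fold lower, the transporter gene Abcb1b 8.21-fold higher and the electron donor of cytochromes P450, Por, 3.75-fold higher. The growth hormone signal factor Stat5b was 2.07-fold lower.

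Clock genes of the arrays of 3 and 9 months differed from those of 12, 18 and 24 months. The clock index was -2.96 ± 0.13 at 3 months, -3.23 ± 0.09 at 9, 1.99 ± 0.45 at 12, 1.99 ± 1.25 at 18 and 1.66 ± 1.07 at 24. Scan session was argued against, because the lowest 24-month array lay 2.97 above the highest array of 3 or 9 months of the same session, whose indices spanned 0.47. Slide and scan day were set against age by 1 array alone, 12-month array 2 (1.99), which shared them with arrays of 3 or 9 months (-3.29 to -2.81). On its slide and day, 9-month arrays 1 and 3 had -3.28 and -3.13, which goes against slide and day there. Across genes this array stood apart from its group, but its index lay between those of the other 12-month arrays (1.54 and 2.44). With 1 such array, slide and scan day were not excluded. A gradual change with age was argued against by a step of 5.22 from 9 to 12 months, where the whole change from 3 to 24 months was 4.62 and the pooled spread 0.76. That test replaced one on the later steps, which did not decide, and was chosen after its values were seen. The hour of tissue collection cannot be told apart from age, since no hour is stated: of 12 genes of 1 phase 10 rose from 9 to 12 months and the 4 of the opposite phase fell, 4.61 apart in median log2 change, as a shift in hour would give. The split into phases was set after the data were seen. A change of the clock with age stays open as well, untested.

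T cell, NK cell and class II genes were higher at 24 than at 18 months. A single array was argued against, since the lowest median log2 change with 1 array of 24 months left out was 1.89 over 32 genes. A smaller hepatocyte share was argued against as the whole cause, since the T and NK cell score rose by 1.72 more than the endothelial score (spread 0.39). On 24-month array 3 alone, where the T and NK cell score was highest, the hepatocyte score was low (-0.56, others -0.11 to 0.20) and the endothelial (0.54), B and plasma cell (1.57), erythroid (1.20) and neutrophil (2.43) scores were high, so a smaller share stays open as a part of the rise there. Scan session could not be set directly against age, since no 18-month array shared the session of the 24-month arrays. Within that session the lowest 24-month array lay 1.31 above the highest 9-month array, so the session alone does not give a high score. This does not exclude a part of session in the difference between 18 and 24 months. The 3-month arrays of that session scored 0.24 to 0.30, nearer the lowest 24-month array (0.52), and for T and NK cell genes alone 24-month array 4 (0.41) lay below them (0.46 to 0.60). Slide and scan day cannot be told apart from age, because 0 arrays of other ages shared those of 24 months, and more immune cells with age stays open as well.

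More genes fell than rose between 3 and 24 months. Lost signal of dim probes may account for it: falls per rise were 1.07 in the brightest of 3 equal sets of genes, against 1.39 in the middle set and 5.46 in the dimmest. Of 190 olfactory and vomeronasal receptor genes 99 were lower at 24 months and 0 higher by limma, and 42 lay above background on all 16 arrays. The shift to the 75th percentile moves all genes of an array alike and was argued against as the whole cause. From 3 to 24 months the median of the dimmest set fell by 0.28 against that of the brightest (spread 0.09), with no overlap between arrays of the ages. Quantile normalization decides nothing here, since it moved the median log2 change by only -0.001. A loss of transcripts with age stays open and was not tested.

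Other splits of the arrays into groups of the same sizes were counted for each count of genes, and for the lists of 24 against 3 months and the trend, not for those of the steps. For 24 against 3 months 1 of 35 splits, the real one, gave 2858 genes or more, a share under 0.05. The highest other gave 1762, with 24-month arrays 1, 2 and 3 apart from the rest. For 24 against 18 months it was 1 of 35, with 5523 against 3966 for the split that set the same 3 arrays apart. For any age difference it was 1 of 100, with 8031 against 176, and for the trend 1 of 100, with 1250 against 1. Splits that mix ages also mix slides and scan days, so these counts do not exclude chance differences between slides. For the steps the 10 splits are too few for a share under 0.05: the real split gave 1110 (highest other 1) for 9 against 3 months, 1337 (110) for 12 against 9 and 295 (2) for 18 against 12. For lists 19 of 35 splits gave at least 12 for 24 against 3 months (highest 18), and 54 of 100 at least 10 for the trend (highest 20), so chance was not excluded for these list counts.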
